A study of Mus musculus with 6 samples.

How the data were processed

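Total RNA from 6 samples of TM4 cells was labelled with biotin and hybridized to an Illumina MouseWG-6 version 2.0 BeadChip, per the labels' protocols. The cells had been transfected with siRNA at a final 0.1 µM. Groups and replicate numbers follow the sample titles: 3 samples with the Gata4 pool and 3 with the non-targeting siRNA. The design text numbers the controls 3 to 6, which conflicts with 3 samples per group, and the titles were followed. The passage is 12 in the sample labels and 13 in the protocol.

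The deposited value table holds 1 intensity per probe and array on a linear scale. GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. About 37.1% of the intensity values lie below 0 and the sorted columns nearly coincide, so the deposited intensities are background-subtracted and quantile-normalized. The authors' deposited table of called probes gives log2 fold changes, mean log2 expression, p-values with adjusted p-values, and a linear fold (ratio), under headers in the style of limma. Its largest adjusted p is 0.0499, and the ratio of adjusted to raw p in the authors' deposited table implies 46251 tested probes. A further 18 columns of per-array values match no sample label and were not used in any step.

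The design fixed before the data were examined called for limma's neqc on non-normalized signals with detection p-values. Those columns match no sample label, so this could not be done, and the deposited intensities took their place. The stand-in was chosen after the files were seen. A trial of 7 other transformations (values floored at 1, the 3 maximum likelihood fits of normexp and the 3 added constants) had by then shown their counts of changed probes, and these were 734 to 2518 when recomputed as alternatives, against 1558 for the setting used. The setting used was normexp with a background mean of 0 and a background SD of 9.40 taken from the values below 0, then an offset of 16 and log2. A fold change of a dim probe is understated on this scale. Probes were tested if they exceeded the noise floor of 17.1, the 95th percentile of the sizes of the values below 0, on at least 3 of 6 arrays.

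Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Every adjusted p of a gene comes from this fit and every adjusted p of a list from camera or fry of limma. A probe above the noise floor on at most 1 array of a group gives a bound (the single array was allowed after the values of Sprr2k were seen), computed as the bright group's mean log2 value against the dim group's mean of, per array, the higher of the floor and the probe's own value. Figures were drawn with matplotlib 3.10.9.

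Gene names came from the authors' deposited table, updated through Entrez numbers with a RefSeq gene table of assembly GRCm38.p6, used for names only. Of 2415 named probes 1740 carried a current symbol, 465 were updated, 195 kept the deposited symbol, 14 were left out because symbol and number disagreed and 1 because its symbol had become a date. Probes deposited under a predicted locus were kept where the Entrez number beside it named a gene, as for Zfpm1, Inhbb, Ldhb, Hk2, Fabp5, Xaf1, Smad6 and Nr1d1, and their sequences were not compared with the genes. A gene was represented by its brightest probe. Of 331 genes with at least 2 named probes, 4 had probes of both signs. Probes outside that table are unnamed here, not without a gene.

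The 23 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Gata4, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose symbol is not a clone name, up to 4 called members of each list (all for the glycolysis, blood-testis barrier and Sertoli lists), and up to 2 members as values where a list has no call. Lists with at least 3 named members were tested with camera at a preset correlation of 0.01. The lists tested held from 16 genes (smooth muscle) to 65 (blood-testis barrier), with from 3 (Sertoli) to 19 (matrix) of them named.

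The tests were tried on simulated data for the Gata4 siRNA comparison with 17740 probes. Of 100 probes changed 1.5-fold 6 were recovered and of 100 changed 2-fold 50, with 1 false call, and with nothing changed 0 were called. Only these probes were changed in the simulation, against 1558 called in the data. With fewer changed probes the adjustment asks for a smaller raw p, so recovery in the data can be higher. How many changes of 1.5-fold are missed in the data was not measured. Alternatives covered the treatment of dim values, the filter, the variance model, array weights, a replicate block, each array left out, the probe rule and the list test. The planned match of siRNA seeds to transcripts was not run, since transcript sequences are not used here.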

Results

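Transcript levels were measured in TM4 cells, an immortalized mouse cell line derived from Sertoli cells, the somatic cells that nurse developing sperm in the testis. The cells had been transfected with a pool of 4 small interfering RNAs (siRNAs) directed at Gata4, a zinc finger transcription factor of the gonads and heart, or with a non-targeting siRNA. Each group had 3 samples, and each sample was hybridized to its own array on an Illumina MouseWG-6 version 2.0 BeadChip. The deposited intensities had been brought to a common distribution, so that the median intensity was 6.8 on Gata4 siRNA array 1 and 6.7 on each of the other 5 arrays. Between 17705 and 17737 of the 45269 probes on an array lay above the noise floor of 17.1 intensity units. Over the 17740 probes tested, Pearson's r across probes was 0.9872 to 0.9932 between arrays of the same group and 0.9779 to 0.9869 between arrays of different groups. The number of arrays, 3 per group, limits the precision of every value given here. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

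The design holds a single comparison, which asks how the transcripts of a Sertoli cell line differ once Gata4 is targeted by siRNA. The level of Gata4 itself was not analysed here, because no probe named in the tables used carries it. The knockdown and the group labels are therefore not checked by the targeted gene. Gata4 is thus also absent from the named genes called lower. All names come from the authors' calls, so no probe named Gata4 is among the probes the authors called changed. A probe without a name here may still measure it. Gene names came only from the authors' deposited table of called probes, so every named gene below had already been selected by the authors for a change on these same samples. Its direction and its membership in a list are thus not independent evidence. A list member that the authors did not call has no name here. Counts of members below are therefore shares of the named members, not of a whole list. Those named were 15 of 47 for glycolysis, 9 of 35 for fatty acid handling and 9 of 47 for TGF-beta signalling. The probes of Zfpm1, Inhbb, Ldhb, Hk2, Fabp5, Xaf1 and Smad6 bear the symbol of a predicted locus in that table and took these names from its Entrez numbers, so a signal from a related locus is not excluded.

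Transcripts differed in both directions between Gata4 siRNA and control cells. Matrix metalloproteinase Mmp10, a secreted protease of the extracellular matrix, was at least 10.7-fold higher, with an intensity of 345.9 ± 52.5 (SD, n = 3) in Gata4 siRNA cells against 10.8 in control cells, where no array rose above the noise floor (adjusted p = 0.00022). Rab15, a small GTPase of endosomal recycling, rose by 2.68 ± 0.14 (log2 fold change ± SE, n = 3 per group; adjusted p = 0.000224). On the falling side, Sprr2k, a small proline-rich protein of the cornified envelope, was at least 7.71-fold lower (adjusted p = 0.00343), with an intensity of 308.6 ± 51.1 (SD, n = 3) in control cells against 48.1 on Gata4 siRNA array 3 and, below the noise floor, 5.6 and 7.2 on arrays 1 and 2. The zinc finger gene Zbtb8b fell by 1.90 ± 0.16 (adjusted p = 0.002).

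Of the 17740 probes tested with limma, 1558 (8.78%) changed at an adjusted p under 0.05, 722 of them higher and 836 lower in Gata4 siRNA cells. Changes of at least 1.5-fold were found for 533 rising and 638 falling probes, and changes of at least 2-fold for 108 and 127. Among 1989 named genes tested, 515 rose, 586 fell and 888 did not pass. Among the 15339 probes without a name here, 169 changed. The count of changed probes moved with single arrays: it was 372 without Gata4 siRNA array 1, 257 without Gata4 siRNA array 2, 487 without control array 1 and 723 without control array 2. It was 1052 without Gata4 siRNA array 3 and 1602 without control array 3. The count also moved with how dim values were treated, from 734 with values floored at 1 to 2518 with 130 added to each value, and to 3079 with array weights. Control array 3 had the lowest of these weights, 0.38, against 0.79 to 1.97 for the other arrays. Its r with the other control arrays was 0.9872 and 0.9875, against 0.9906 or more for every other pair within a group. Single calls moved too: of the 89 named genes followed over the alternatives, 45 lost their call without Gata4 siRNA array 2, 25 with a replicate block and 21 with values floored at 1.

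The authors' deposited table lists 2415 probes, 1231 with a positive and 1184 with a negative log fold change, and does not state its direction. All 2401 of its probes that were tested here had the same sign as the Gata4 siRNA minus control difference, which sets its direction. Across these probes Pearson's r between the log2 fold changes was 0.9562 and the slope of the values here on those of the authors' deposited table was 1.35. Both analyses start from the same arrays. At an adjusted p under 0.05, 1389 of the 2401 probes were called here as well.

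Further large rises included H2bc4, a core histone H2B gene, at 2.30 ± 0.20, and the serum and glucocorticoid regulated kinase Sgk2 at 2.28 ± 0.17 (log2 fold change ± SE). The long non-coding RNA Dleu2 rose by 2.26 ± 0.13 and the tetraspanin-like Tm4sf4 by 2.08 ± 0.19. Sgk2, Dleu2, Tm4sf4 and the guanylate-binding protein gene Gbp2b were above the noise floor on 2 of the 3 control arrays. The membrane glycoprotein Gpnmb rose by 2.04 ± 0.20, the membrane-anchored semaphorin Sema7a by 1.87 ± 0.21 and Btbd11 by 1.80 ± 0.17. Ass1, argininosuccinate synthase of arginine synthesis, rose by 1.71 ± 0.17. The adjusted p-values of these genes lay between 0.000349 for Dleu2 and 0.00417 for Sema7a.

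Further large falls included Unc13a, a vesicle priming factor, at -2.02 ± 0.30, and the secreted angiopoietin-like protein Angptl6 at -1.70 ± 0.21. The second small proline-rich gene, Sprr1a, fell by 1.73 ± 0.20, and corneodesmosin, Cdsn, fell to 0.354 of the control level (adjusted p = 0.00772). Stanniocalcin, Stc1, a glycoprotein hormone, fell by 1.66 ± 0.16 and the transcription factor Klf4 by 1.66 ± 0.24. Galnt18, a glycosyltransferase that starts O-linked glycans, was at least 2.27-fold lower, since no Gata4 siRNA array rose above the noise floor (intensity 9.0 ± 2.5, SD, n = 3; adjusted p = 0.00524). The adjusted p-values of the 12 largest falls lay between 0.002 for Zbtb8b and 0.00948 for Unc13a. In all 12 largest rises and all 12 largest falls the 3 arrays of each group were separated, which is part of the rule that chose them. Chance alone separates 3 values from 3 in 10% of genes.

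**Figure D1:**
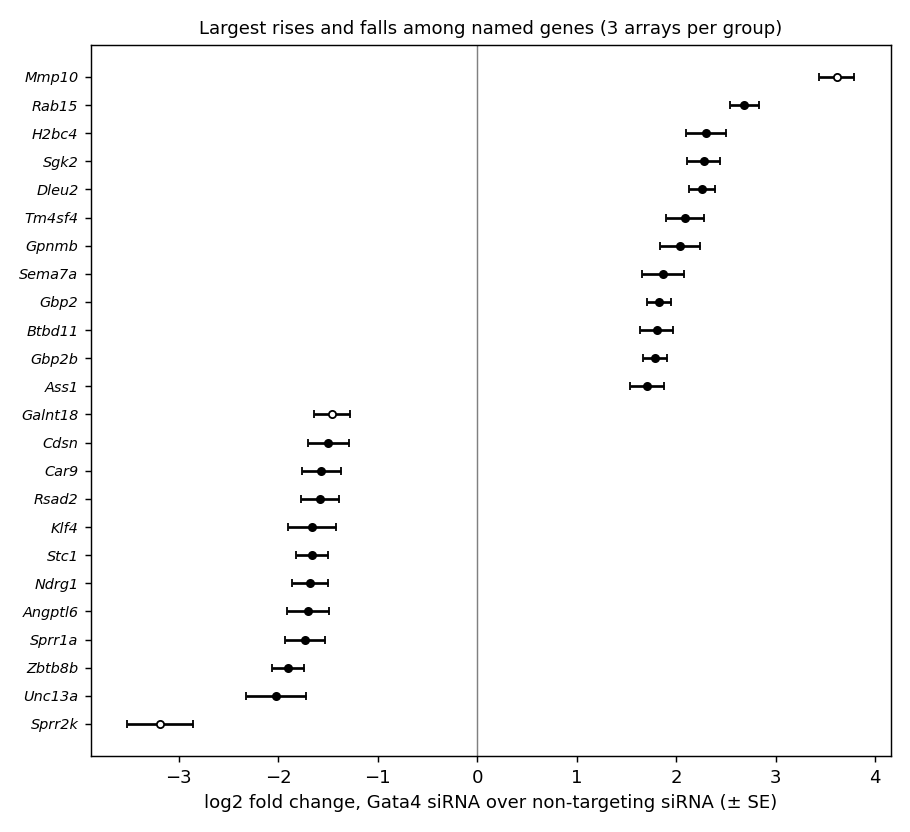
Log2 fold change, Gata4 siRNA over non-targeting siRNA, with its standard error (x axis) for the 12 largest rises and 12 largest falls among named genes (y axis), 3 arrays per group. Open circles mark Mmp10 and Galnt18, whose dim group lay below the noise floor on every array, and Sprr2k, whose dim group lay below it on 2 of 3, with lower bounds of the fold of 10.7, 2.27 and 7.71.

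Named genes of the hypoxia response, 16 of the 26 in the list, fell together. Of 16 named members, 0 rose, 11 fell and 5 did not pass, and the median log2 fold change was -0.66 (camera adjusted p = 0.00113; adjusted p = 0.27 with an estimated correlation). Ndrg1, a stress-induced gene of differentiation, fell by 1.68 ± 0.18 and carbonic anhydrase Car9, which handles acid at the cell surface, by 1.57 ± 0.20. Ankrd37 fell by 1.31 ± 0.17 and the transcriptional repressor Bhlhe40 by 0.82 ± 0.12. The angiogenic factor Vegfa was at -0.27 ± 0.11 (adjusted p = 0.161). The mean of the list separated the groups, from -0.51 to -0.25 on the Gata4 siRNA arrays and from 0.35 to 0.45 on the control arrays, with Gata4 siRNA array 3 nearest the controls.

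Glycolysis and lactate handling was also lower, with 1 of 15 named members rising, 9 falling and 5 not passing and a median of -0.67 (camera adjusted p = 0.017; adjusted p = 0.27 with an estimated correlation). Lactate dehydrogenase B, Ldhb, fell by 1.27 ± 0.14, to 0.413 of the control level. The glycolytic enzymes Pgam1, Gpi1 and Eno2 fell by 0.83 ± 0.17, by 0.80 ± 0.16 and by 0.70 ± 0.15. The glucose transporters Slc2a1 and Slc2a8 fell by 0.67 ± 0.12 and by 0.72 ± 0.17, and glycogen synthase Gys1 fell by 0.71 ± 0.17. Of the pyruvate dehydrogenase kinases, which restrain entry of pyruvate into the mitochondrial cycle, Pdk3 and Pdk1 fell by 0.74 ± 0.11 and by 0.56 ± 0.14 while Pdk4 rose by 1.42 ± 0.22. Adjusted p-values of these 10 genes ran from 0.00388 for Ldhb to 0.0439 for Gys1. Slc2a1, Pdk1 and Hk2 belong to the hypoxia list too. Of 4 named members of the tricarboxylic acid cycle and respiratory chain, Idh2 fell by 0.65 ± 0.17 (adjusted p = 0.0495) and 3 did not pass (camera adjusted p = 0.471).

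Named genes of cholesterol synthesis and sterol uptake, 11 of the 26 in the list, were lower as well. Of 11 members, 8 fell and 3 did not pass, and the median was -0.50 (camera adjusted p = 0.00783; adjusted p = 0.27 with an estimated correlation). Phosphomevalonate kinase Pmvk fell by 1.01 ± 0.12, the sterol dehydrogenase Nsdhl fell by 0.92 ± 0.12, lanosterol synthase Lss by 0.56 ± 0.11 and Dhcr7 by 0.55 ± 0.12. In fatty acid and lipid handling 1 of 9 named members rose, 5 fell and 3 did not pass, with a median of -0.48 (camera adjusted p = 0.043; adjusted p = 0.27 with an estimated correlation). Lipoprotein lipase Lpl fell by 0.85 ± 0.12, the fatty acid carrier Fabp5 by 0.94 ± 0.15 and the desaturase Scd2 by 0.67 ± 0.11. The coactivator Ppargc1a rose by 0.98 ± 0.16. The call of this list ended without control array 1 (camera adjusted p = 0.0513).

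**Figure D2:**
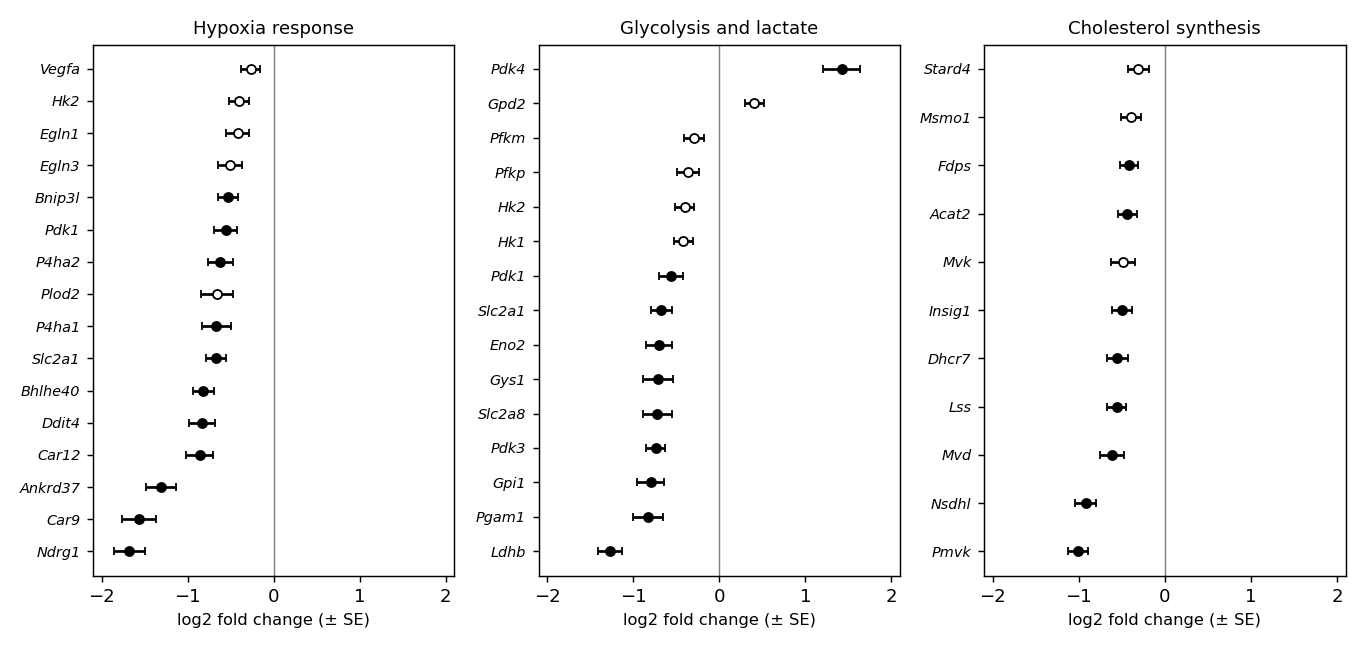
Log2 fold change, Gata4 siRNA over non-targeting siRNA, with its standard error (x axis) for the named members (y axis) of the hypoxia, glycolysis and cholesterol lists, 3 arrays per group. Filled circles passed an adjusted p of 0.05 and open circles did not. All 16 hypoxia and all 11 cholesterol members lie below 0, and in the glycolysis list Pdk4 and Gpd2 lie above 0.

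The basement membrane and extracellular matrix list held 59 genes, and the 19 named ones were mostly lower. Of 19 named members 2 rose, 8 fell and 9 did not pass, with a median of -0.56 (camera adjusted p = 0.0126; adjusted p = 0.27 with an estimated correlation). The fibrillar collagens Col1a1, Col1a2 and Col3a1 fell by 1.24 ± 0.14, by 1.06 ± 0.13 and by 1.05 ± 0.13, and fibrillin Fbn1 fell by 1.04 ± 0.11. In TGF-beta, activin and BMP signalling 0 of 9 named members rose, 6 fell and 3 did not pass, and the median was -0.53 (camera adjusted p = 0.0126; adjusted p = 0.27 with an estimated correlation). Ccn2, a matricellular protein induced by TGF-beta, fell from an intensity of 14466 ± 234 to 7546 ± 501 (SD, n = 3). The inhibitory Smad6, which was above the noise floor on 2 of the 3 Gata4 siRNA arrays, fell by 0.97 ± 0.18 and the follistatin-like Fstl1 by 0.72 ± 0.14.

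The cell cycle and DNA replication list held 61 genes, and the 13 named ones were mostly higher. Of 13 named members 7 rose, 1 fell and 5 did not pass, with a median of 0.55 (camera adjusted p = 0.017; adjusted p = 0.27 with an estimated correlation). E2f2, a transcription factor of S phase entry, rose by 0.83 ± 0.12, the origin licensing factor Cdc6 by 0.73 ± 0.13 and the ribonucleotide reductase subunit Rrm2 by 0.61 ± 0.12. Cyclin D2, Ccnd2, fell by 0.95 ± 0.16. Among cell cycle inhibitors and p53 targets 2 of 5 named members fell, Cdkn2b by 0.75 ± 0.15 and Gadd45a by 0.50 ± 0.11, and 3 did not pass (camera adjusted p = 0.0614).

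Named smooth muscle and peritubular myoid markers, 5 of 16 in a list fixed for cells that surround the tubule, were higher as well. Of 5 named members 4 rose and 1 did not pass, and the median was 0.72 (camera adjusted p = 0.0444; adjusted p = 0.27 with an estimated correlation). Tagln rose by 0.93 ± 0.15, Actg2 by 0.73 ± 0.12, Mylk by 0.72 ± 0.16 and smooth muscle actin Acta2 by 0.53 ± 0.12. Acta2 had an intensity of 11686 in control cells. The call of the list ended without control array 1 (camera adjusted p = 0.0536) and without control array 3 (camera adjusted p = 0.0567). These markers moved with the same groups as the lists above. Of the macrophage and leukocyte markers Cd14 was at 0.39 ± 0.12 (adjusted p = 0.0804), and of the germ cell and endothelial lists 0 members were named.

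Only 3 of the 52 genes in the Sertoli list were named, and these moved apart. Of 3 named members of the Sertoli list, the transcription factor Sox9 rose by 0.59 ± 0.11, while the inhibin and activin subunit Inhbb fell by 0.53 ± 0.12 and the tight junction scaffold Tjp1 by 0.67 ± 0.16 (camera adjusted p = 0.647). Junction genes of the blood-testis barrier, the seal between Sertoli cells, went both ways: 3 of 12 named members rose, 4 fell and 5 did not pass (camera adjusted p = 0.959). The tight junction claudin Cldn12 fell by 0.65 ± 0.13, the adhesion receptor Cxadr by 0.70 ± 0.15 and the polarity protein Pard6a by 0.66 ± 0.17, whereas Cgnl1, Pkp4 and Ybx3 rose by 0.81 ± 0.14, by 0.54 ± 0.12 and by 0.56 ± 0.14. The list median was -0.01, and its sign turned in several alternatives.

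In the GATA list, Gata3, a related zinc finger factor, fell by 1.36 ± 0.12 (adjusted p = 0.002) and the GATA cofactor Zfpm1 by 0.81 ± 0.12 (adjusted p = 0.0101). In lists with fewer than 3 named members, Lrp8 of the ovarian list fell by 0.67 ± 0.13, Fdxr of the steroidogenesis list by 0.98 ± 0.13 and Fzd7 of the Wnt list by 0.61 ± 0.15, while Fzd5 was at -0.43 ± 0.13 (adjusted p = 0.082). Among genes of the RNA interference machinery Dgcr8 rose by 0.65 ± 0.11 and Prkra fell by 0.56 ± 0.12.

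Interferon and cytokine genes went both ways. Of 12 named members of the type I interferon list 6 rose, 4 fell and 2 did not pass (median 0.56; camera adjusted p = 0.503). The guanylate-binding protein Gbp2 rose by 1.83 ± 0.12, Xaf1 by 1.30 ± 0.19 and Ifi35 by 0.80 ± 0.12, whereas the antiviral Rsad2 fell by 1.58 ± 0.19 and was above the noise floor on 2 of the 3 Gata4 siRNA arrays. Of 8 named members of the cytokine and chemokine list, not all of them cytokines, 1 rose, 5 fell and 2 did not pass (median -0.74, camera adjusted p = 0.232). The chemokine Cxcl1 rose by 1.56 ± 0.12, and Cxcl12, Tnfaip3 and Ccl9 fell by 0.81 ± 0.11, by 0.77 ± 0.13 and by 0.71 ± 0.14. In the unfolded protein and integrated stress response 7 of 13 named members fell and 6 did not pass (camera adjusted p = 0.0614). Trib3 fell by 1.13 ± 0.15, Vldlr by 0.90 ± 0.13, the cystine transporter Slc7a11 fell by 0.85 ± 0.16 and Chac1 by 0.63 ± 0.11.

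**Figure D3:**
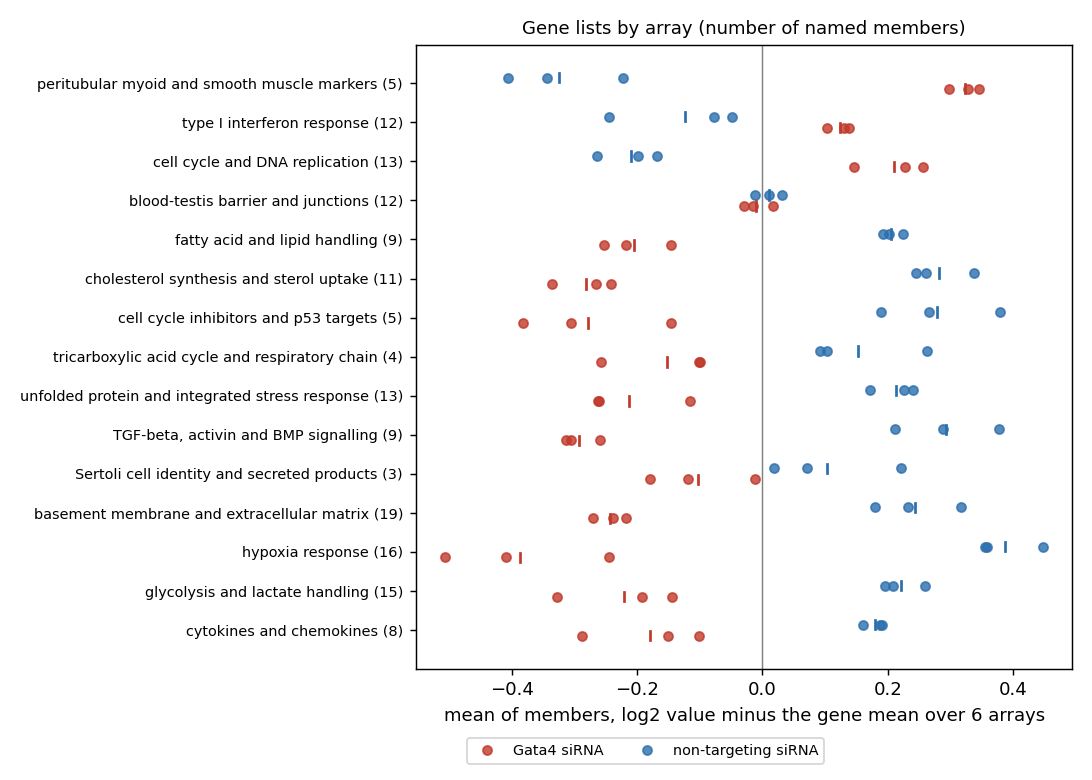
Mean over the named members of each list of the log2 value minus the gene's mean over the 6 arrays (x axis), with 1 point per array and a bar at each group's mean, for the 15 lists with at least 3 named members (y axis, number of members in brackets). The hypoxia list runs from -0.51 to -0.25 on the Gata4 siRNA arrays and from 0.35 to 0.45 on the control arrays, and the arrays of the blood-testis barrier list overlap.

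Across the 15 lists tested, camera called 8 with a preset correlation of 0.01, 2 higher and 6 lower, and 0 with a correlation estimated for each list. The estimated setting also takes its degrees of freedom from the 6 arrays, while the preset one takes them from the named genes. The fatty acid list had an estimated correlation of -0.033, below the preset, yet its camera adjusted p went from 0.043 to 0.27. The loss of calls is thus not due to correlation between genes alone. fry, which asks whether the members of a list move one way on balance without comparing them with other genes, called 13. camera here compares a list with the other named genes only, all of which the authors had called. Adjusted over the list alone, every named member of every list passed, in lists that camera called and in those it did not. The authors had selected these genes on the same samples, so that count is not independent evidence and tells no list from another.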

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

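The alternatives with offset 50, the maximum likelihood fits of normexp, plain added constants, cyclic loess and without both arrays numbered 3 were chosen after seeing the data; the others were planned. Against 1558 changed probes (722 higher, 836 lower; 515 named genes higher, 586 lower), values floored at 1 gave 734 (357 and 377; 275 and 267), the replicate block 736 (351 and 385; 259 and 266), eBayes with trend and robust 2384 (1161 higher; 837 named genes higher), array weights 3079 (1496 and 1583; 787 named genes higher), the maximum likelihood fit with offset 50 2408 (1178 higher; 851 named genes higher), and 130 added to each value 2518 (1265 higher; 955 and 925 named genes). With offset 50, 1108 probes and 785 named genes were higher, and without both arrays numbered 3, 315 named genes were higher. No filter gave 1116, a stricter filter 1898, the maximum likelihood fit 1940 with offset 16 and 1559 with offset 1, 16 and 50 added 1335 and 2126, cyclic loess 1558 and leaving out both arrays numbered 3 1238. Leaving out 1 array gave 257 (without Gata4 siRNA replicate 2) to 1602 (without control replicate 3) changed probes, 128 to 776 higher, 129 to 826 lower, 104 to 443 named genes higher and 96 to 490 lower; fewer arrays are part of the cause. Of the 1558 probes, 257 were shared without Gata4 siRNA replicate 2 and 1550 with array weights. Same-numbered samples did not deviate together (r of -0.05, -0.09 and -0.01), so the block rests on a shared number only. Gata4 siRNA samples 1, 2 and 3 did deviate weakly with control samples 2, 3 and 1 (r of 0.22, 0.15 and 0.15). Whether those pairs shared a batch was not tested.

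The 8 lists called by camera became 0 with an estimated correlation, at an adjusted p of 0.27 each, with medians as before: hypoxia -0.66, glycolysis -0.67, matrix -0.56, TGF-beta -0.53, cholesterol -0.50, fatty acid -0.48, cell cycle 0.55 and smooth muscle 0.72. fry called 13, adding the tricarboxylic acid cycle (-0.51), cell cycle inhibitors (-0.50), interferon (0.56), cytokines (-0.74) and the stress response (-0.52). The stress response also passed with the mean over a gene's probes (-0.52), the maximum likelihood fit with offset 50 (-0.48) and 130 added (-0.45), and cell cycle inhibitors in the last of these (-0.48) and the one before it (-0.49). Both also passed without control replicate 2 (-0.49 and -0.52; adjusted p = 0.0485 each). The fatty acid list missed with the replicate block (-0.48; adjusted p = 0.0511) and, with smooth muscle, without both arrays numbered 3 (-0.62 and 0.66; adjusted p = 0.0538 each). The blood-testis barrier median of -0.01 turned to 0.0014 with array weights, 0.0027 with 130 added, 0.0185 without both arrays numbered 3 and as far as 0.0302 when 1 array was left out (-0.046 to 0.0302), and was never called. With 1 array left out 6 to 10 lists passed, and medians ran over -0.72 to -0.59 (hypoxia), -0.69 to -0.54 (glycolysis), -0.64 to -0.45 (matrix), -0.59 to -0.45 (TGF-beta), -0.55 to -0.48 (cholesterol), -0.59 to -0.43 (fatty acid), 0.48 to 0.62 (cell cycle), 0.59 to 0.80 (smooth muscle), -0.55 to -0.47 (cell cycle inhibitors) and -0.56 to -0.49 (stress response). The cause of these moves was not tested.

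The stricter filter left 11 of the 89 named genes followed untested. In the alternatives that tested them 0 turned direction, and of the 78 tested in all 31 kept their call throughout; of the 89, 10 to 45 lost it without 1 array, most without Gata4 siRNA replicate 2, 25 with the replicate block, 21 each with values floored at 1 and without both arrays numbered 3, 11 with no filter, 5 with the mean over a gene's probes, and 4 and 2 with 16 and 130 added. Not run were neqc on the non-normalized signals, cyclic loess or median scaling in place of quantile normalization, a slide block, seed lengths and any setting for Gata4. Signal over background limits what can be said of dim genes.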

Other observations

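All tests in this part were chosen only after the results they bear on had been seen, and the gene groups of the next paragraph were picked after their values were seen, so they show no enrichment.

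Of enzymes that modify and fold collagen, the prolyl hydroxylases P3h1, P4ha1 and P4ha2 fell by 0.87 ± 0.11, by 0.67 ± 0.16 and by 0.62 ± 0.14 (log2 fold change ± SE, n = 3 per group), the collagen chaperone Serpinh1 by 0.82 ± 0.12 and the procollagen protease Adamts2 fell by 0.86 ± 0.13, while Plod2 was at -0.66 ± 0.18 (adjusted p = 0.0609). P4ha1, P4ha2 and Plod2 belong to the hypoxia list too and are counted there. Of the collagens in the matrix list, Col6a2, Col6a1, Col4a1 and Col5a1 did not pass (adjusted p of 0.059 for Col6a2 to 0.154 for Col5a1). Of clock genes, Per1 and Cry2 fell by 0.78 ± 0.16 and by 0.89 ± 0.16, Nr1d1, from a probe deposited under a predicted locus, rose by 0.91 ± 0.13 and Dbp was at -0.74 ± 0.20 (adjusted p = 0.0579). The glutathione S-transferases Gstm1, Gstm2 and Gstm5 fell by 0.78 ± 0.20, by 0.77 ± 0.16 and by 0.78 ± 0.13; such near-identical paralogs can share signal.

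The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of these, the real one, gave as many as 1558 changed probes, while the highest of the others gave 0. Each other split mixes both groups on each side, so a steady difference between the groups adds to the spread there. Their 0 is therefore not a measure of calls by chance. With 10 splits a share under 0.05 cannot be reached.

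The hypoxia and glycolysis lists were lower together by camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.27 each). The fall of named glycolysis members was not confined to the 3 shared ones, since of the 12 outside the hypoxia list 7 fell. The mean of these 12 minus that of other named genes differed between the groups by -0.42 ± 0.06 (log2 ± SE, 3 arrays per group). The authors had selected all 12 for a difference on these same arrays, which can narrow that SE. It is thus no independent test of the glycolysis list. This comparison of arrays was added after a permutation over genes was known, in which the 12 had a median of -0.70 against 0.29 for other named genes (one-sided permutation p = 0.00172 over 100000 resamples, among genes the authors had called). That p takes genes as independent, which the estimated correlation of 0.13 for the glycolysis list does not support. Changes near 0 are missing among named genes by the same selection, so the 0.29 is not a typical change. Nor was the fall confined to dim probes: of the 18 named members of either list with a mean intensity over 1000, 17 were lower, with a median of -0.67. Bright members without a change could not enter, since the authors' smallest log fold change was 0.20 in size. The size of this median therefore does not test an effect of background. Wells that differed in cell density or spent medium could give the same picture and cannot be told apart from the siRNA, as the lowest control array lay 0.60 above the highest Gata4 siRNA array on the hypoxia mean and nothing in the labels records density. An effect of the siRNA on these genes also stays open and was not tested.

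Gata4 siRNA array 3 lay nearer the controls. Over 2176 probes picked on the other arrays its slope was 0.70, and 0.70 outside the hypoxia list against 0.77 or more on the other 5 arrays. The low slope thus extends to probes other than those of the named hypoxia genes. These genes are few among the probes, so the slope could hardly move without them and the outcome was nearly fixed in advance. Hypoxia genes outside the list, or without a name here, are not excluded. A fixed limit used at first, which 2 control arrays also missed, was replaced after the slopes were seen by the comparison with the other arrays. For falling probes array 3 had 0.63 against 0.74 or more elsewhere, but for rising probes 0.79, level with the lowest of the others at 0.79, so a smaller response in both directions stays open. RNA of control cells in this sample, or a weaker knockdown, could also give this: the slopes of rising and falling probes differed by 0.16, which decides neither.

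Of 9 named histone H2B genes 8 rose, with a median of 1.10 against 0.55 for the cell cycle and replication list (two-sided permutation p = 0.00082). By the limit first set, that p counted against a larger share of cells in S phase. The limit was changed after the p was known, because 8 of the 9 genes lie within 2 standard errors of their mean and may be a single measurement. The H2B genes rose by more than the list, and how far histone transcripts rise with S phase was not tested. With the change, S phase stays open. Cross-hybridization between these paralogs also stays open: H2bc4 departs from the mean by 5.22 standard errors, yet the other 8 do not separate.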
